A study of Mus musculus with 16 samples.

How the data were processed

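RNA sequencing was done on B cells sorted from the peritoneal cavity, in C57BL/6 mice. Per the labels' protocols, B-1a cells were taken as CD19+, B220 low, CD43+, CD5+ and CD11b high, and B-2 cells as CD19+, B220 high, CD43−, CD5− and CD11b low. The mice carried floxed Elavl1, the gene of the RNA-binding protein HuR, either without Cre (WT) or with Cre driven from mb1 (KO). Total RNA was isolated with a micro column kit, low-input libraries were made, and paired-end reads of 100 bases were sequenced on a DNBSeq instrument. The 16 libraries form 4 groups, with 4 of B-1a WT, 5 of B-1a KO, 4 of B-2 WT and 3 of B-2 KO. The labels do not say whether libraries with the same number came from the same mouse.

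Per the submitters' processing notes, the tools were cutadapt 3.4, Trim Galore 0.6.7, FastQC 0.11.9, STAR 2.7.5a, SAMtools 1.9, R 4.0.2 and DESeq2 1.28.1, with no role or order stated. The notes name both GRCm39 and mm10, so no coordinates are given here beyond the chromosome. The counting step, the annotation and the model formula are not given in the sources used here. The authors deposited 1 table of 28735 genes and 16 columns, whose name calls the values normalised counts. The signal values the authors deposited were found, from the values themselves, to be a model's fitted means and not measurements of single libraries; how they were written out is not given in the sources used here. After genes and columns were centred on the log2 scale, only 4 singular values stood above rounding error. The 16 columns fell into 7 sets of proportional columns, and the SD of the log2 ratios within a set was at most 2.9e-15 (columns were called proportional below 1e-06). Each deposited value is therefore a library factor times a fitted level of the group, times a second fitted term with 2 levels. The term acts alike in every group that holds both levels. The second term separates 4 libraries (B-1a WT 1, B-1a KO 1 and 4, B-2 WT 1; its minority level) from the other 12 (its common level). Xist is low and Y-linked genes are high in the 4, the pattern of male cells, and the other 12 show the pattern of female cells. All B-2 KO libraries form 1 set of columns and were placed at the common level by their fitted values of Xist and Ddx3y.

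Fitted values hold no spread between replicates. No test between groups, no p-value and no mean ± SD could be computed, although a moderated linear model with an adjusted p under 0.05 had been chosen before the data were examined. The differences below are computed from the deposited model's fitted levels after scaling and with a pseudocount of 1, so at low levels they are not the model's own estimates. Their only error given here is a counting SE, computed as if each fitted value were a Poisson count of reads with no biological variation. It is a lower limit, since differences between mice add to it. The SE leaves out the pseudocount, so at low levels it is not the error of the printed difference. With 1000 reads per library, a 2-fold difference would equal 1.96 SE at a coefficient of variation between mice of 0.52 in the B-1a comparison, 0.45 in the B-2 comparison and 0.34 in the difference between them. The column sums, which stand in for depth, ran from 22149577 to 40754614. They were 23505625 to 40754614 in B-1a WT, 22149577 to 35791580 in B-1a KO, 28320760 to 40126199 in B-2 WT and 24823961 to 34599588 in B-2 KO.

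Columns were scaled by median-of-ratios factors, which ran over genes with a fitted value of at least 10 in at least 3 libraries (15907 genes). Group levels were taken at the common level of the second term, that of the libraries with the female pattern. Differences are log2(level + 1), so the pseudocount of 1 understates the fold of low genes. Where levels are low in 1 cell type only, it can also overstate the difference between the cell types. Genes were counted as higher or lower at 2-fold or more, over all 15907 genes and over those with a mean level of at least 50 in the groups compared. Of the gene IDs, 28656 (99.7%) matched the GENCODE mouse annotation used for biotypes, transcript lengths and 3′ UTRs. The genes named follow the rule fixed before the data were examined, without its p criterion. Elavl1, Cd79a and the genes of the sorted proteins are always given. Per comparison the 10 largest differences in each direction (5 for the difference between cell types) are taken among genes with a mean level of at least 50, without predicted genes, pseudogenes and antigen receptor segments. Up to 4 members of each described list are given, those with the largest difference. Genes outside this rule are marked as chosen after their values were seen.

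For 29 gene lists fixed before the data were examined, the median difference was set against the medians of 10000 random lists of the same size, drawn from 20 bins of expression level. Of these lists, 26 had at least 3 measured genes. The mitochondrially encoded list had 0, the granulocyte list 1 and the mesothelial list 2. A median outside the middle 95% of the random medians describes these fitted values and is not a test across mice. About 1.3 of the 26 lists would lie outside by chance in each comparison if the genes of a list varied independently. Genes that vary together within a list would put more lists outside, and some lists share genes, so 1.3 is no measure of chance between mice. The alternatives tried were 2 pseudocounts, 2 filters and TMM factors (trims of 30% and 5%), and, added after the data were seen, column totals and the minority level of the second term.

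The procedure was tested on simulated counts of 15907 genes with 200 changed genes. The changed genes were drawn from those with a mean level of at least 50, and the fit was given the true dispersion. A 4-fold gene counted as recovered if its estimate was at least 2-fold in the right direction. All simulated 4-fold genes (100%) met this in both comparisons of KO-labelled with WT libraries. With counting error alone, 1 unchanged gene with a mean level of at least 50 reached 2-fold in the B-1a comparison and 2 in the B-2 comparison. With a dispersion of 0.1 between mice, 17 and 84 did. In the simulation the mean level was taken over all 4 groups and not only over those compared. These counts therefore cover a different set of genes from the observed counts. Over all levels 20 and 45 unchanged genes reached 2-fold from counting error alone, and 86 and 202 with that dispersion. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.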

Results

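B-1a cells are the innate-like B cells of the body cavities, and B-2 cells are the conventional, follicular type. The series addresses how HuR, which binds U-rich and AU-rich sites in RNA, controls B-cell signalling and the upkeep of innate B cells. Both B-cell types were sequenced from mice without Cre (WT, 4 libraries of each type) and from mice with the mb1-driven Cre (5 B-1a and 3 B-2 libraries). The deposited values are fitted group levels and carry no spread between replicates, so sizes are given with a counting SE and no test.

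Elavl1 itself (ENSMUSG00000040028, chromosome 8) was not lower in the libraries labelled KO. Its fitted level was 6717 in the B-1a WT libraries 2, 3 and 5 and 6768 in library 1. It was 8219 in the KO-labelled B-1a libraries 2, 3 and 5 and 8391 in libraries 1 and 4. In B-2 cells it was 6243 in WT libraries 2, 3 and 4, 6377 in WT library 1 and 8161 in all 3 KO-labelled libraries. The KO-labelled level was thus 1.22-fold higher in B-1a cells (log2 0.29 ± 0.01, counting SE) and 1.31-fold higher in B-2 cells (0.39 ± 0.01). A value per gene includes reads from exons that a floxed allele keeps, so it does not show whether the deletion took place. The libraries are therefore called KO-labelled in these results, except where a library is given by its name. Cd79a (ENSMUSG00000003379, chromosome 7), the mb1 gene whose locus carries the Cre, was 2.94-fold lower in KO-labelled B-1a cells (109758 against 37357) and 2.38-fold lower in KO-labelled B-2 cells (108436 against 45604). Cd19 was nearly level between the genotypes, with log2 differences of 0.07 in B-1a and 0.10 in B-2 cells. Ptprc, which encodes B220, differed by −0.05 and −0.19, Spn (CD43) by 0.09 and 0.41, Cd5 by −0.28 and 0.14, and Itgam (CD11b) by −0.67 and −0.21.

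**Figure D1:**
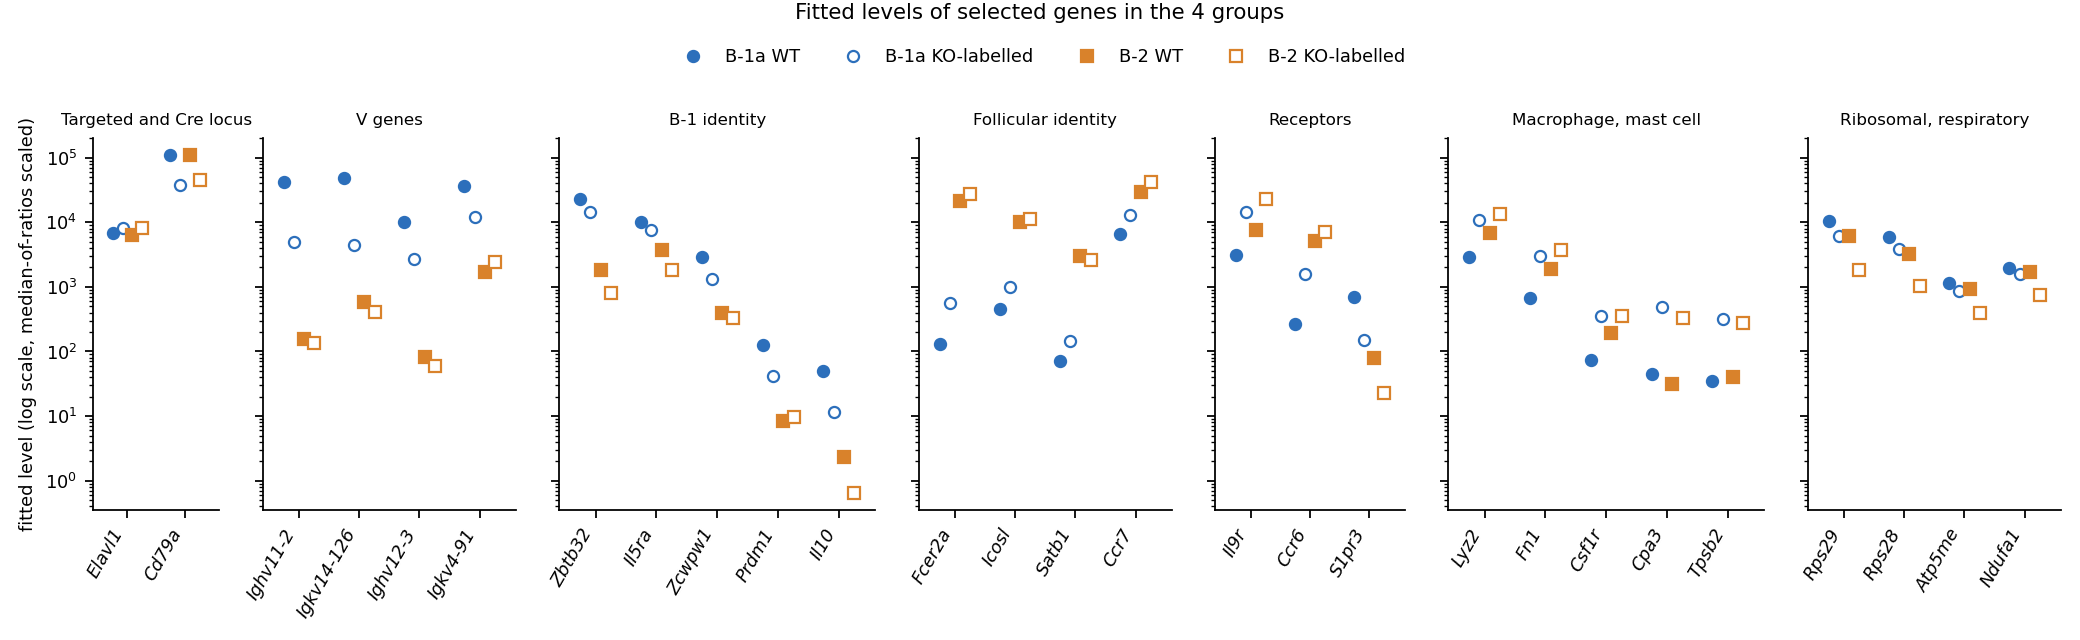
Fitted levels of selected genes in the 4 groups (vertical axis logarithmic, in median-of-ratios scaled units); circles are B-1a cells, squares B-2 cells, filled symbols WT and open symbols KO-labelled. Each symbol is 1 fitted level with no error bar because the values carry no replicate spread; Cd79a is lower and Elavl1 is higher in both KO-labelled groups (genes drawn were chosen after their values were seen).

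The WT libraries give the reference for the 2 cell types. B-1a cells had higher levels of 18 of the 20 B-1 identity genes by at least 2-fold (median log2 2.81), and 10 of the 18 follicular identity genes were at least 2-fold lower in them (median −1.46). Ighv11-2, a heavy-chain V gene used by B-1a antibodies to phosphatidylcholine, had a level of 41376 in B-1a and 157 in B-2 cells. Igkv14-126 (47822 against 582) and Ighv12-3 (9968 against 81.8) showed the same contrast. V gene values are uncertain, since V genes form multigene families of near-identical copies. Fcer2a, the low-affinity IgE receptor CD23 of follicular B cells, was 165-fold lower in B-1a cells (129 against 21357), and Cr2, the complement receptor CD21, was 17.3-fold lower. The genes of the sorted proteins had log2 differences of 3.37 for Spn, 5.91 for Cd5, 2.11 for Itgam, −0.63 for Ptprc and −0.14 for Cd19. Spn, Cd5 and Itgam are on the B-1 identity list, so their part in its contrast follows from the sort and is no finding. Of the genes with a mean level of at least 50, these included, 892 were at least 2-fold higher in B-1a cells and 685 lower. Over all 15907 genes the counts were 1581 and 1319.

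The 10 genes furthest above their B-2 level in WT B-1a cells were Cd3g, Igsf9b, Fras1, Fzd6, Etl4, Klhl41, Ccl22, Kcnj5, Pstpip2 and Gnb3. Cd3g, a chain of the T-cell receptor complex, reached 943 in B-1a against 1.79 in B-2 cells, although its partner Cd3e stood at 9.28 and the receptor constant gene Trac at 22.5 in the same B-1a group. Pstpip2 reached 2045 against 16.6, and Gnb3, a G-protein beta subunit, 2675 against 23.2. The 10 genes furthest below were Flt3, Fcer2a, Rflnb, Itgb3, Emid1, Pxdc1, Prss12, Zfp608, Vpreb3 and Lrrk2. Flt3, a cytokine receptor of progenitors and dendritic cells, had a level of 2490 in B-2 and 12.7 in B-1a cells, and Lrrk2, a kinase, 8655 and 173. Ribosomal protein genes were higher in B-1a cells in 76 of 77 cases (median log2 0.63, Rplp0 1.02), respiratory chain genes in 68 of 71 (0.24) and glycolysis genes in 18 of 23 (0.38, with Slc16a3 1.51 and Tpi1 1.31). Short transcripts of no list were also higher, with a median of 0.23 for genes matched to the ribosomal protein list on the longest transcript and level and 0.17 for those matched to the respiratory chain list. The plasma cell and secretory list had a median of 0.43, with Jchain at 4.06 and Tent5c at 3.23 but Sdc1 at −2.84. Cytokines and their receptors went both ways, with 10 members at least 2-fold higher (Csf2rb2 4.93, Il10 3.92) and 7 lower, around a median of −0.49. In all, 9 of the 26 lists lay above and 6 below the middle 95% of random lists, among them also the BCL2 family (0.34), Toll-like receptor signalling (0.25), cholesterol synthesis (−0.30), NF-kB (−0.18) and the ELAV and AU-rich element binding proteins (−0.18). The macrophage list was among those lower in B-1a cells (−1.03), with Fn1 at −1.49 but Mrc1 at 3.27 and Cd68 at 2.82, while T and NK markers were higher (1.33).

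In KO-labelled B-1a cells the antigen receptor V genes typical of this cell type had lower fitted levels. Igkv14-126 was 10.9-fold lower (4401 against 47822), Ighv11-2 8.40-fold lower (4928 against 41376), Ighv11-1 4.49-fold lower and Ighv12-3 3.65-fold lower. Of the 7 V genes measured, 5 were at least 2-fold lower (median log2 −1.87). The B-1 identity list had a median of −0.51, with 16 of 20 genes below 0 and 3 at least 2-fold lower. These were Il10 (50.1 to 11.5 in level, log2 −2.04 ± 0.21, counting SE), Prdm1, the plasma cell regulator Blimp-1 (−1.58 ± 0.12), and Zcwpw1 (−1.18 ± 0.02), and the next was Pstpip2 (−0.92). The follicular identity list had a median of 0.26, above the random range, but its genes were divided, with 10 of 18 above 0 and 8 below, 3 at least 2-fold higher and none 2-fold lower. Fcer2a was 4.41-fold higher (571 against 129), Icosl 2.23-fold, Satb1 2.01-fold and the lymph node homing receptor Ccr7 1.97-fold. All 4 stayed under their level in WT B-2 cells, Fcer2a far under it (21357 there) and Ccr7 less so (13130 against 29044).

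Over all genes of the B-1a comparison, 767 were at least 2-fold higher and 335 lower in KO-labelled libraries. With a mean level of at least 50 there were 234 and 176 of 11622, and 52 and 42 at 4-fold. The levels of 90.6% of these genes lay within 1.5-fold of each other. The count of higher genes over all levels depended on the filter, with 366 at a minimum value of 50 and 1400 with no filter. The highest by size were Sema6d, Mctp1, Wnt10a, Cpa3, Pcdh9, Vwf, Tpsb2, Ppargc1a, Trps1 and Ttn. Mctp1, a calcium-binding membrane protein, differed 17.1-fold (6.64 against 129.5), Wnt10a, a Wnt ligand, 14.4-fold (7.62 against 123) and the transcription factor Trps1 7.45-fold (166 against 1246). Cpa3 and Tpsb2 are mast cell proteases, at 11.0-fold and 9.02-fold. The lowest were Fam174b, Igsf9b, Cavin1, Chit1, Camk2n1, Kndc1, Klhl41, Cttn, Gnb3 and Dusp14. Fam174b was 32.3-fold lower (418 to 12.0), Igsf9b 24.4-fold (742 to 29.5), Gnb3 7.89-fold (2675 to 338) and the phosphatase gene Dusp14 7.25-fold. The counting SE of these 20 log2 differences was between 0.04 and 0.31.

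Several receptors for cytokines and chemokines differed at least 2-fold in B-1a cells. Of 34 cytokine and cytokine receptor genes, 6 were at least 2-fold higher and 1, Il10, was lower. Il9r, the interleukin-9 receptor, was 4.69-fold higher (3077 against 14427) and Il12a 2.40-fold. Il7r, which is also on the list of T and NK markers, was higher by log2 2.38, from a level of 4.29. Of the 28 adhesion and chemokine receptor genes, Ccr6 was 6.09-fold higher (262 against 1604). S1pr3 was 4.56-fold lower (694 against 152), S1pr2 3.20-fold and Ccr9 2.15-fold. B-cell receptor signalling genes had a median near 0 (−0.05; percentile 81.8 of random lists), with the exchange factor Rasgrp3 at 1.65, Cd79a at −1.55, Akt3 at 0.56 and Akt1 at −0.55. Their inhibitors had a median of −0.20 (20 of 30 below 0), with Ubash3a at 1.46, Lair1 at 1.41, Dok2 at −1.23 and Sla2 at 0.84. Interferon-stimulated genes had a median of −0.23 (29 of 38 below 0; Rsad2 −0.98, Ifit1bl1 −0.90, Oas2 0.82, Ifit3 −0.81). Smaller medians under the random range were those of cholesterol synthesis (−0.21; Ldlr −0.66, Dhcr7 −0.44), the plasma cell and secretory list (−0.20; Prdm1 −1.58, Eaf2 −0.78), glycolysis (−0.19; Tpi1 −0.70), Toll-like receptor signalling (−0.17), ribosomal proteins (−0.17) and the respiratory chain (−0.17, 70 of 71 below 0). For the ribosomal and respiratory lists this is about as much as in genes of no list matched on the longest transcript and level, whose medians were −0.19 and −0.15. The medians of immediate early genes (0.05), the cell cycle (0.02), the TCA cycle (−0.14), adhesion and chemokine receptors (−0.13) and p53 targets (−0.14) lay within the random range. Among p53 targets Plk2 was 3.57-fold lower and Fas 2.77-fold higher. No gene of the cholesterol, glycolysis, ribosomal and respiratory lists differed 2-fold. With column totals the median of all genes shifts by 0.11, and the B-cell receptor signalling median is then 0.06.

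Markers of other cell types were also higher in KO-labelled B-1a cells. Of 22 macrophage markers, 16 were at least 2-fold higher and none 2-fold lower (median log2 1.82). Mafb was 5.26-fold higher, Csf1r 4.63-fold (74.3 against 348), Fn1 4.52-fold (668 against 3022) and Lyz1 4.35-fold, and Lyz2, the most abundant of those named and chosen after its values were seen, had levels of 2870 and 10810. Of 7 mast cell markers, 6 were at least 2-fold higher (median 2.76), with Cpa3 at 44.1 against 495, Tpsb2 at 34.6 against 320.5, and Cma1 and Mcpt4 likewise. T and NK markers had a median of 1.04 with 8 of 15 at least 2-fold higher and 1, Cd3g, lower (943 to 406; chosen after its values were seen). The higher ones started from low levels (Il7r 4.29 against 26.5, Trbc2 4.52 against 18.6, Ccl5 8.09 against 29.4, Zap70 53.7 against 210). All 3 lists lay above the range of random lists, as did the follicular, cytokine, NF-kB (median 0.01) and ELAV and AU-rich element binding protein lists (0.03).

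In KO-labelled B-2 cells ribosomal protein genes and respiratory chain genes had lower fitted levels. Of 77 ribosomal protein genes 76 lay below 0 and 13 were at least 2-fold lower (median log2 −0.61). Rps29 was 3.38-fold lower (6101 to 1806), Rps28 3.08-fold, Rps21 differed by log2 −1.45 and Rpl38 by −1.44. Of 71 respiratory chain genes 66 lay below 0 and 6 were at least 2-fold lower (median −0.47), namely Atp5me (−1.25), Ndufa1 (−1.16), Ndufa3 (−1.11) and 3 others. Genes of no list with the longest transcript under 600 nucleotides also had a lower median here (−0.64, 45 genes). Interferon-stimulated genes had a median of −0.36, with 33 of 38 below 0 and 4 at least 2-fold lower, which were Ifit3b (−1.82), Ifit3 (−1.43), Ifit1 (−1.36) and Rsad2 (−1.20). Cholesterol synthesis genes were below 0 in 21 of 24 cases (median −0.23; Tm7sf2 −0.74, Ldlr −0.72), and cell cycle genes in 31 of 40 (−0.12; Aurkb −0.74, Cenpf −0.52).

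Mast cell markers were at least 2-fold higher in KO-labelled B-2 cells in 7 of 7 cases (median 2.40; Cpa3 10.1-fold, Kit 7.49-fold, Tpsb2 6.88-fold, Cma1 5.29-fold), and macrophage markers in 6 of 22 (median 0.91; Fcgr1 1.91, Mertk 1.295, C1qa 1.17, Cd14 1.15). The most abundant macrophage gene named, Lyz2 (again chosen after its values were seen), had levels of 6704 in WT and 13435 in KO-labelled B-2 cells. Red cell markers were lower (median −1.17; Hba-a2 −1.32, Hbb-bs −1.25). B-cell receptor signalling genes had a small positive median of 0.06 at percentile 99.7, although Cd79a (−1.25) was the only member 2-fold apart. NF-kB pathway genes lay above the random range too, with a median of 0.07. The B-1 identity list had a median of −0.16, with Zbtb32 (−1.21), Il10 (−1.04 ± 1.12, counting SE) and Il5ra (−1.03) lower and Cd9 (1.67) higher, and the V gene list one of −0.23. In all, 4 lists lay above and 8 below the random range. The follicular list (−0.05) lay within it, as did T and NK markers (−0.06), the inhibitors of B-cell receptor signalling (−0.09), the plasma cell list (−0.09), glycolysis (−0.06), the TCA cycle list (−0.03), Toll-like receptor signalling (−0.01), cytokines (0.06) and adhesion receptors (−0.11).

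Across the B-2 comparison, 445 genes were at least 2-fold higher and 316 lower in KO-labelled libraries (145 and 124 with a mean level of at least 50, and 17 and 7 at 4-fold). The higher count over all levels was 220 at a minimum value of 50 and 951 with no filter. The highest were Vwf, Cpa3, Hspg2, Rab3b, Ccser1, Tpsb2, Nav2, Cma1, Adgrl2 and Sik1. Vwf, the von Willebrand factor of endothelium and platelets, differed 29.9-fold (13.5 against 433), Hspg2, the basement membrane protein perlecan, 9.95-fold (63.4 against 640) and the small GTPase gene Rab3b 9.16-fold (14.1 against 137). Sik1, a kinase induced by cyclic AMP, differed 4.84-fold (340 against 1652). The lowest were Cxcr3, Gad1, Car2, Ncs1, Myo1f, Sdc1, Gsr, Ifit3b, Shank1 and Rflnb. The chemokine receptor gene Cxcr3 was 8.19-fold lower (119 to 13.6), Gad1, which makes GABA from glutamate, 7.72-fold, and the myosin gene Myo1f 4.57-fold (1442 to 315). Their counting SE was between 0.04 and 0.23.

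**Figure D2:**
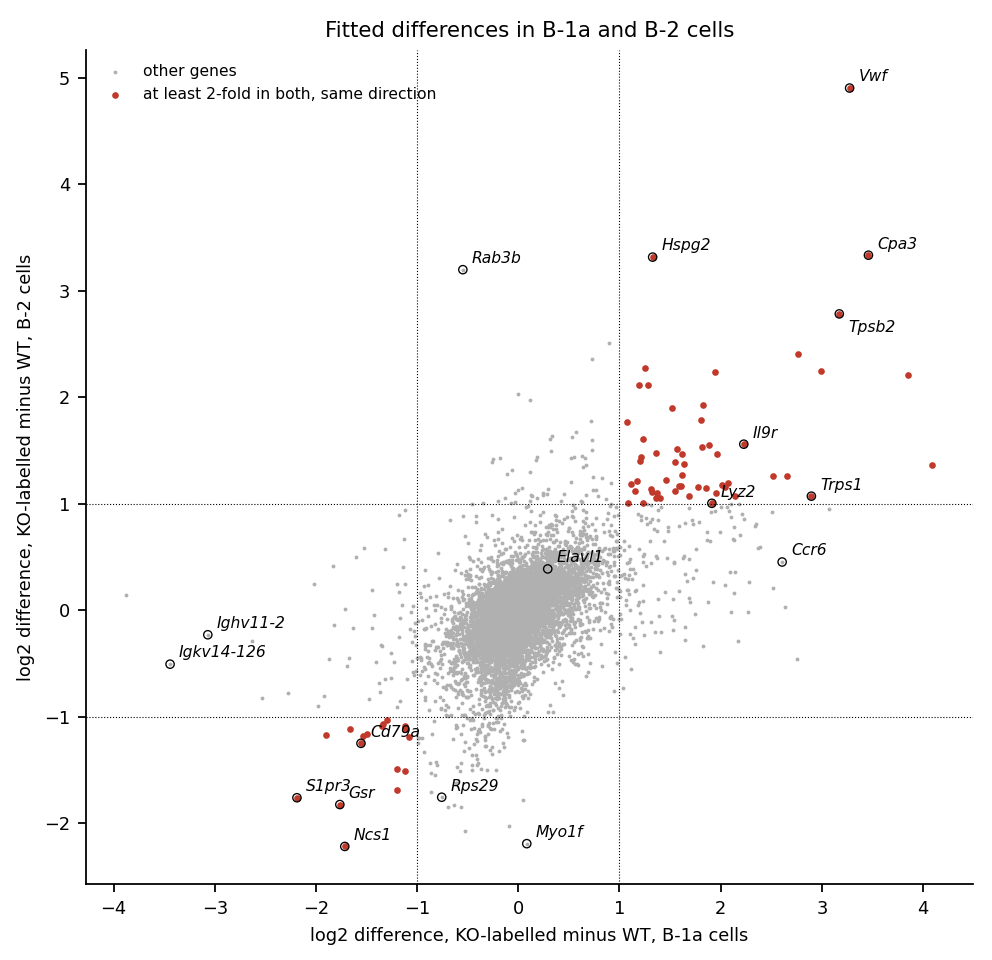
Log2 difference between KO-labelled and WT levels in B-1a cells (horizontal) and in B-2 cells (vertical) for the 11025 genes with a mean level of at least 50 in both comparisons; dotted lines mark 2-fold. Red points are the 72 genes at least 2-fold apart in both with the same direction, and circled genes were chosen for labels after their values were seen; Ighv11-2 and Igkv14-126 lie far to the left near 0 on the vertical axis.

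The differences in both cell types went together across genes. Over the 11025 genes with a mean level of at least 50 in each comparison, Pearson's r was 0.55 and Spearman's rho 0.53 across genes, which are not independent replicates. The 2 comparisons share no libraries, but the model's second term is common to both. Whether the 2 cell types came from the same mice is not known, and shared mice would add to the agreement. Libraries B-1a KO 1 and B-2 KO 1 did not share a mouse, as the first has the male and the second the female pattern. Of 201 genes at least 2-fold higher in B-1a and 111 in B-2 cells, 55 were shared, where independent lists would share 2.0. Of 74 and 110 lower genes, 17 were shared, where 0.7 would be. Of the 55 shared higher genes, 22 (40%) were also lower by at least 0.5 along the second fitted term, as most macrophage and mast cell markers were, so RNA of other cells may add to this agreement. Among these 11025 genes none was at least 2-fold higher in one cell type and lower in the other; Plcb4, under the level of 50 in B-2 cells, was (5.39-fold lower in B-1a and 2.49-fold higher in B-2 cells). Shared higher genes included Cpa3, Tpsb2, Vwf and Il9r (2.94-fold in B-2 cells), and shared lower genes Cd79a, S1pr3 (3.39-fold in B-2 cells), Ncs1 and Gsr, which encodes glutathione reductase (log2 −1.76 in B-1a and −1.83 in B-2 cells).

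The genes whose difference was not alike in the cell types included the transcription factor Spic, which was 9.87-fold higher in KO-labelled B-1a cells (7.89 against 86.7) and 1.20-fold lower in B-2 cells. By the log2 difference of the differences, B-1a minus B-2, the largest positive values belonged to Spic (3.56 ± 0.28, counting SE), Car2 (3.26 ± 0.38), Ttn (3.25 ± 0.25), Mctp1 (2.73 ± 0.31) and Gad1 (2.67 ± 0.22). The largest negative values were those of Fam174b (−3.86 ± 0.93), Plcb4 (−3.75 ± 0.38), Rab3b (−3.74 ± 0.20), Igsf9b (−3.42 ± 2.01) and Nherf2 (−2.98 ± 0.21). Fam174b and Igsf9b were lower in KO-labelled B-2 cells too (3.37 to 0.96 and 1.68 to 0.18), at levels where the pseudocount shrinks the fold. The size of their difference between the cell types therefore rests on the pseudocount, in part for Fam174b and for the larger part for Igsf9b. In this comparison 637 genes were at least 2-fold more positive and 449 more negative (207 and 164 with a mean level of at least 50). Among the lists outside the random range, the most negative were the V genes (−2.10) and the B-1 identity list (−0.37), followed by glycolysis (−0.20), Toll-like receptor signalling and the TCA cycle list (both −0.12), and B-cell receptor signalling lay just inside the random range (−0.10, percentile 2.9). The most positive were red cell markers (0.84), macrophage markers (0.79), T and NK markers (0.69, but −0.29 under the filter at 50), ribosomal proteins (0.45), follicular identity (0.37), the respiratory chain (0.32), interferon-stimulated genes (0.10) and cell cycle genes (0.25; Stmn1 1.03, Ccne2 0.98).

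**Figure D3:**
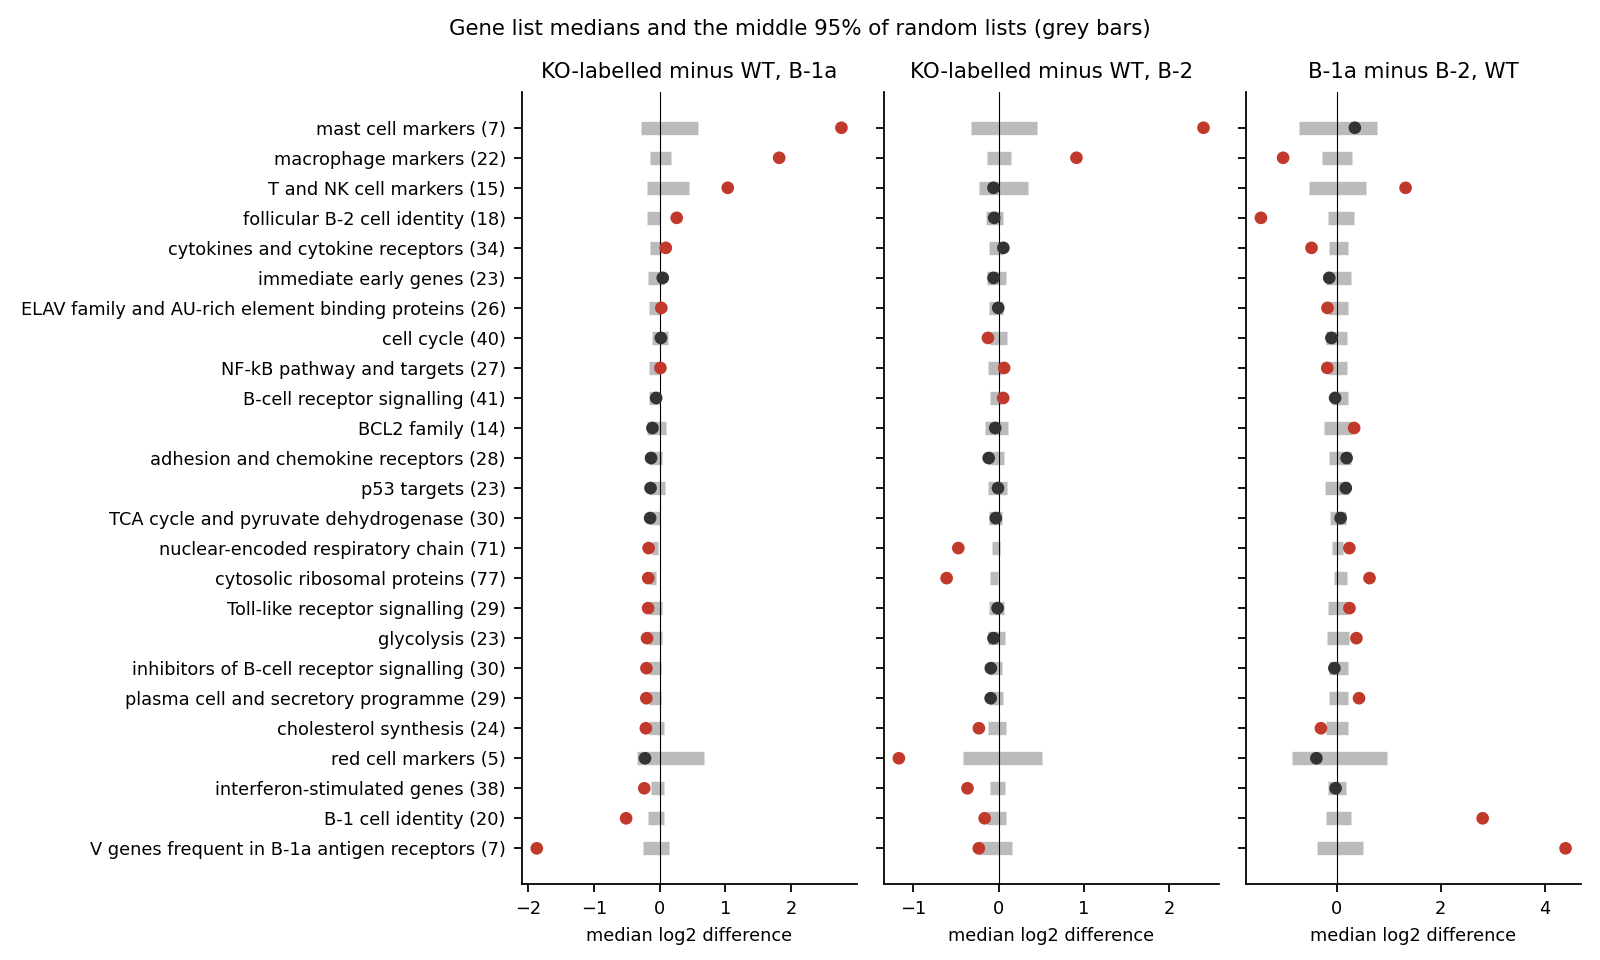
Median log2 difference of 25 gene lists (number of measured genes in parentheses) in 3 comparisons; grey bars span the middle 95% of the medians of 10000 random lists matched on expression level, and red points lie outside it. Mast cell and macrophage markers lie to the right in both KO-labelled comparisons, ribosomal and respiratory chain genes lie furthest to the left in B-2 cells apart from red cell markers, and V genes in B-1a cells; the sex-linked list is left out.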

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

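The tests of marker genes along the second fitted term, of B-2 cells among sorted B-1a cells, of dilution and of transcript length were chosen after the result was seen, and the test on all higher B-1a genes was fixed before. The column sum of KO-labelled B-1a library 2, 22149577, stood apart from the other 4 of its group, with a gap of 0.768 of the group's range where 0.71 marks an outlying value; chance gives this in about 1 group of 20. Plcb4, a phospholipase C, had opposite differences in the 2 cell types, 5.39-fold lower in KO-labelled B-1a cells (371 to 68.0) and 2.49-fold higher in KO-labelled B-2 cells (5.29 to 14.7, both low levels). The log2 difference between them, −3.75 ± 0.38 (counting SE), was not tested against the spread between mice.

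Macrophage and mast cell markers were higher in both KO-labelled groups, although the sort took CD19+ cells. RNA of macrophages and mast cells in the sorted B cells is a candidate source. If so, the markers could also go together along a split of the libraries that is not the genotype. Along the second fitted term, which follows Xist and Y-linked genes, 27 of the 29 markers (93.1%) were lower at its minority level, with a median log2 of −1.40. Interferon-stimulated genes (36 of 38) and cell cycle genes (34 of 40) were lower there too, so such a drop is not particular to these markers. Lyz2 and Fn1, chosen after their values were seen, differed there by −2.15 and −2.04. Of the genes at least 2-fold higher in KO-labelled B-1a cells, 79 of 234 (33.8%, against 5.0% of all genes at that mean level) were lower by at least 0.5 along that term, and 155 were not. That share was under the one fixed beforehand as a sign of such RNA. Of the 176 genes at least 2-fold lower in KO-labelled B-1a cells 21.0% were also lower along the term, so this drop is not confined to the higher genes. The 155 genes do not exclude RNA of other cells, which need not drop along the term. T and NK markers had a median of 0.10 along it, although 8 of 15 were at least 2-fold higher in KO-labelled B-1a cells. Uptake or expression of the macrophage and mast cell transcripts by B cells, and a change in the number of macrophages and mast cells in the mice labelled KO, stay open and untested.

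Genes typical of B-1a cells were lower in KO-labelled B-1a cells. B-2 cells in the B-1a sort would have to give 29.7% of the RNA to produce the median of the B-1 identity list and 72.6% to produce that of the V genes, if B-2 cells lacked these transcripts. The 48 genes at least 4 log2 units higher in WT B-2 than in WT B-1a cells argue against this, as they reached a median of only 4.9% of their level in KO-labelled B-2 cells (quartiles 2.05% and 9.13%; 2.36% in WT). The WT value is low by the choice of these genes, so it is no baseline for the 4.9%. The argument covers the fall of B-1a genes only. A share of B-2 RNA of that size could still raise strongly B-2-biased genes such as Fcer2a (571 in KO-labelled B-1a and 27448 in KO-labelled B-2 cells), which was not tested. Dilution by RNA of other cells would lower all B-cell transcripts about alike, but the B-cell receptor signalling list had a median of −0.05 against −0.51. A shift in the makeup or state of the B-1a pool of the mice labelled KO stays open and untested, because the levels carry no spread between mice and the Cre itself goes with the genotype.

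Ribosomal protein and respiratory chain genes were lower in KO-labelled B-2 cells (median −0.51 over 148 genes), and their transcripts are short. Genes of no list matched to them on median transcript length and level had a median of −0.07, but that match was poor, because the longest transcripts of these genes had a median of 2302 nucleotides against 907 for the lists. By the bounds set for the test, a median of −0.26 or lower would speak for a bias against short transcripts, and one above −0.13 against it. The first match thus spoke against it, and the length measure was changed after this was seen. Matched on the longest transcript instead, genes of no list had a median of −0.20 (955 nucleotides), between the bounds, which decides neither way. Members under 600 nucleotides had a median of −0.96 (30 genes) and the others −0.40 (118 genes), and genes of no list under 600 nucleotides had −0.64. A loss of short transcripts may account for part of the pattern, and the rest cannot be told apart from a difference between the genotypes, since all 3 KO-labelled B-2 libraries share 1 fitted level.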

How the results depend on the processing

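The column totals and the minority level of the second term were chosen after seeing the data; the other settings were planned. Over 7 settings 3 of the 98 named differences changed sign, all of at most 0.05 in size, namely Cd79a between WT cell types (0.017), Cd19 in the difference between the comparisons (−0.027) and Ptprc in the B-1a comparison (−0.052, and 0.063 with column totals). That the 75 of at least 2-fold kept their sign says little, because most were named for their large size. The number of gene lists outside the random range ran from 15 to 17 in the B-1a comparison, 12 to 16 in B-2 cells, 13 to 16 for the difference and 14 to 15 between WT cell types. With TMM factors, column totals, a pseudocount of 0.5 or the minority level, each count of 2-fold genes was within 1.5 times the main one. A pseudocount of 5 gave 269 higher and 201 lower genes in the B-2 comparison and 403 higher genes for the difference, as it shrinks the folds of low genes. With no filter on low values there were 1400 higher and 652 lower genes in the B-1a comparison, 951 and 629 in the B-2 comparison and 1565 and 1214 for the difference. With a fitted value of at least 50 in at least 3 libraries there were 366 and 190, 220 and 191, and 263 and 220, and 1044 higher and 848 lower genes between WT cell types, since fewer genes were counted. That filter turned the median of the T and NK markers in the difference to −0.286, because it removes the markers with low levels; column totals moved the BCL2 family median in B-1a cells from −0.11 to 0.005, within their shift of 0.11 for all genes. Of the other values, 112 moved and 1328 stayed within their counting error or 0.1.

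No paired analysis was possible because fitted means hold no spread between libraries, so no test could be fitted. For the same reason the planned linear models without trend or with quality weights, the count tests, the fits on fewer groups, the index term, the blocks by number or index, the set tests and leaving out each replicate were not run. The libraries' own scaling was not kept as an alternative, since the deposited values are not scaled to equal depth. Genes with levels near 0 in one group, such as Igsf9b in B-2 cells, have counting SEs of up to 2.01 and are the least certain of those named.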

Other observations

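The split of libraries by the second fitted term follows sex-linked genes (genes named here were chosen after their values were seen). Xist, the RNA of the inactive X chromosome in female cells, was lower by log2 −7.90 in the 4 libraries at the minority level, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher by 9.17, 9.13, 8.86 and 8.49. The 4 libraries thus have the pattern of male cells and the others that of female cells. Anything else that differs between these libraries cannot be told apart from sex. Along this term 14 genes with a mean level of at least 50 were at least 2-fold higher and 112 lower. Interferon-stimulated genes were lower in 36 of 38 cases (median −0.34; Ifit3 −1.18, Mx1 −1.17), cell cycle genes in 34 of 40 (−0.44; Birc5 −1.48, Plk1 −1.08) and macrophage markers in 20 of 22 (−1.40). Immediate early genes were higher in 20 of 23 (median 0.44; Fos 1.57, Atf3 1.11) and ribosomal protein genes in 75 of 77 (0.19). The 4 libraries are B-1a WT 1, B-1a KO 1 and 4 and B-2 WT 1, so no KO-labelled B-2 library stands at this level.

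Genes strongly biased to 1 cell type in WT had medians of opposite sign in KO-labelled B-1a cells, but part or all of this may come from the choice of the sets. The B-1a WT level picks the sets and enters the KO-labelled difference with opposite sign, which alone moves counts, medians and correlation this way, and no split of those libraries was possible. Of 404 genes at least 4-fold higher in WT B-1a than in WT B-2 cells (mean level of at least 50 in the WT groups), 103 were at least 2-fold lower and 5 higher (median −0.48). Of 203 genes at least 4-fold higher in WT B-2 cells, 2 were lower and 70 higher (median 0.69). A small share of B-2 RNA in the B-1a sort could add to these rises, which was not tested. In B-2 cells 39 of the 404 were lower and 48 higher (median −0.01), and 15 of the 203 lower and 7 higher (−0.05). With a mean level of at least 50 required in each comparison of KO-labelled with WT cells instead, which drops genes low in B-2 cells, 26 of 193 B-1a-biased genes were lower and 2 higher in B-1a cells (median −0.37), and 8 lower and 25 higher in B-2 cells (−0.03). Of 125 B-2-biased genes, 2 were lower and 42 higher in B-1a cells (0.69), and 5 lower and 4 higher in B-2 cells (−0.06). Under that filter the B-1a difference and the WT cell type difference had a Pearson correlation of −0.46 across genes.

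The hypothesis that transcripts with U-rich 3′ UTRs have lower levels when HuR is missing was put to the KO-labelled libraries. The test ran across 10022 genes with an annotated 3′ UTR, with a prediction fixed before the result. Spearman's rho between the density of AUUUA and UUUUU and the log2 difference was 0.145 in B-1a cells (0.11 after adjustment for 3′ UTR length) and 0.014 in B-2 cells (−0.024 adjusted). A negative rho of at least 0.1 in size had been required in both, so these levels give no sign that such transcripts were lower as a class in the KO-labelled libraries. Median transcript length itself went with the differences (rho 0.218 in each cell type) and was not adjusted for, so it may mask an effect. The test covers fitted steady-state levels and motif density only, and binding of HuR was not analysed here. Elavl1 was not lower in the KO-labelled libraries, so the values do not show that HuR was missing. If it was not, the result says nothing about its loss.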
